A study of Mus musculus with 11 samples.

How the data were processed

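The series holds 11 mouse samples. Of these, 4 RNA samples came from cortical cells electroporated with an ST18 knockdown construct and 4 from cells given a non-targeting control, electroporated at embryonic day 12.5 and collected by GFP sorting at embryonic day 16.5. These 8 RNA libraries were not analysed here. The other samples were 2 chromatin immunoprecipitation (ChIP) libraries made with an antibody to the HA tag and 1 input library of genomic DNA, from cultured cells that the labels call TN. A molecule label of the input sample names HA ChIP, as for the ChIP samples, while its title and description call it input. The ChIP over input ratios rest on the latter. The submitters' processing notes name TopHat2 2.0.8, HTSeq 0.5.4p1, edgeR, Bowtie, MACS2 2.0.10.20120913 and the mouse build mm9, without saying which tool made which file. The aligner settings and any removal of duplicate reads are not given in the sources used here.

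The deposited promoter table gives whole-number read counts in 21881 windows of 1000 bp, 1 window per gene symbol, in 1 ST18 column and 1 input column. The sources used here do not state where a window lies around the transcription start, or whether the ST18 column pools both ChIP libraries. The deposited log2 enrichment was recomputed from the counts: the log2 of (0.4055 times the ST18 count plus 16) over (the input count plus 16) gave the deposited value within 1e-06 in all 21881 windows. The pseudocount of 16 is above the median input count of 7, so it pulls the log2 enrichment of most windows towards 0, and a log2 value of 1 stands for a count ratio well above 2-fold.

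The deposited peak list was made with MACS2 without a control library, at a q cutoff of 0.05, per the file headers. These give a tag size of 50 bp, a fragment length of 48 bp and a local background over 10000 bp. That fragment length is shorter than the tag, so it is a value of the peak caller and may not be that of the DNA fragments. The list rests on 37201269 tags and an effective genome of 1870000000 bp, per the file headers. The alignment it was called on is not named in any label, so the libraries behind it are not named here. The labels list the peak list under the input sample, and the promoter table under a ChIP sample, so the peaks may not be those of the ST18 ChIP. Each peak carries its pileup (the signal in tags at the summit), its fold enrichment over the local background of the same alignment and its −log10 p and −log10 q, all as deposited by the authors. These are values of the peak and were used only to describe and filter the list.

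The design fixed before the data were examined included a limma test over both ChIP replicates, their correlation and fits without each replicate. With 1 ST18 column these could not be made, and the fixed fallback was used: the count of windows with a log2 enrichment of at least 1, with no test. Each named window was given the fold of its ST18 to input ratio over the ratio of all promoters, with an exact (Clopper-Pearson) 95% binomial interval. Where the input count was 0, the fold was taken against a floor of 3 counts. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. Windows named for being highest or lowest were picked by the same counts. That choice exaggerates their folds, and the intervals do not correct for it. An exact two-sided binomial test of each window against the ratio of all promoters, with Benjamini-Hochberg adjustment over all windows, was added after the data were seen. It compares the reads of the deposited columns, not the conditions, since no replicates were available. What counting error alone gives was measured in 100 simulated tables in which every window kept its reads and both columns had the same ratio everywhere.

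The 23 gene lists were also fixed before the data were examined: the ST18 family, apical progenitor, intermediate progenitor, neuronal differentiation, cortical layer, neuronal migration, axon guidance, synapse, epithelial-mesenchymal transition, Notch and Wnt, cell cycle, chromatin repressors, ribosomal protein, apoptosis and inflammation, HOX clusters, pluripotency, astrocyte, oligodendrocyte, microglia, endothelial and mesenchymal, muscle and liver, germ line and olfactory receptor. The median log2 enrichment of each list was placed among the medians of 10000 random lists of the same size, which describes these libraries only. The two-sided share of random lists at least as far out was adjusted over the 23 lists by the Benjamini-Hochberg method. Random lists matched on total reads were added after the data were seen, first within 10 groups of windows and then on the exact number of reads. The second was added because the first put 511 windows without reads into the lowest group, which was used for some of the olfactory receptors.

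The genes named were St18, Myt1 and Myt1l, the 10 symbols with the highest enrichment that were not predicted genes, microRNAs or small nucleolar RNAs, the 10 peaks with the highest fold, and, for each list, the 4 highest members and the lowest one, of which the text prints the lowest and 1 or more of the highest. Any other gene or family was chosen after its values were seen, and is said to be so. Of the 21881 symbols, 21688 matched a GRCm38 gene name, and that annotation was used only for which genes neighbour each other. No mm9 annotation was used here, so peaks were not assigned to genes. Peaks at promoters, gene lists among genes with a peak, and promoter enrichment of genes with and without a peak were therefore not computed.

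The methods were tested on simulated data. Among 100 windows per fold size, drawn 20 times from the real counts, 0.7% of those given a true 2-fold enrichment and 56.6% of those given a 4-fold one reached a log2 enrichment of 1. For lists of 26 genes, 72% of the draws with a 1.25-fold change and 100% of those with a 1.5-fold change lay above the central 95% of random lists, as did 8% of the draws with no change (50 draws each). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.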

Results

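ST18 is a zinc finger transcription factor of the MYT1 family, and the study's ChIP libraries address where it binds in the genome. The data given for analysis were read counts at the promoters of 21881 genes for the HA-tagged ST18 ChIP and its input, and a list of 9381 peaks. The ST18 column held 438960 reads and the input column 160443, with medians of 20 reads (interquartile range 14 to 26) and 7 reads (5 to 10) per window. No reads fell in 523 windows. No replicates were available for any value, since the table has 1 ST18 column for the 2 labelled ChIP samples, which may hold either or both, and 1 input column. The 4 ST18 knockdown and 4 control RNA libraries were not analysed here.

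The first comparison asked which promoters carried more ST18 ChIP reads than input reads. Of the 10 named genes with the highest enrichment, 4 encode protein chaperones and 2 encode Wnt receptors, groups that were noticed after the values were seen. Hsph1, a heat shock protein of the Hsp110 class, ranked first at a log2 enrichment of 1.21, with 86 ST18 reads against 6 input reads, a ratio 5.24-fold that of all promoters (exact 95% interval 2.31 to 14.7). The other chaperone promoters were Cct3, a subunit of the cytosolic chaperonin, at 1.10 (66 against 4 reads, 6.03-fold, 2.25 to 22.8), Hspe1, the mitochondrial co-chaperonin, at 1.10 (124 against 15 reads, 3.02-fold, 1.76 to 5.56), and Hspa8, the constitutive Hsp70, at 1.05 (104 against 12 reads, 3.17-fold, 1.74 to 6.33). Fzd1 and Fzd2, which encode Frizzled receptors for Wnt ligands, stood at 1.13 (106 against 11 reads, 3.52-fold, 1.89 to 7.27) and 1.12 (89 against 8 reads, 4.07-fold, 1.98 to 9.71). All these windows were picked as the highest by the same counts, which raises their folds, and the intervals do not correct for that choice.

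The remaining named genes were Ctdsp2, a phosphatase that acts on the tail of RNA polymerase II, at 1.06 (89 against 9 reads), Tnrc18 at 1.04 (72 against 6), Uspl1 at 1.03 (61 against 4) and the zinc finger gene Zfp467 at 0.96 (47 against 2). In all, 12 of the 21881 windows reached a log2 enrichment of 1. They included Mir207 at 1.18 (72 against 4 reads), 5730422E09Rik at 1.10 (61 against 3) and 1700021C14Rik at 1.03 (66 against 5), which the naming rule left out and which were chosen after their values were seen. The windows of 1700021C14Rik and Cct3 belong to neighbouring genes and may share reads.

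**Figure D1:**
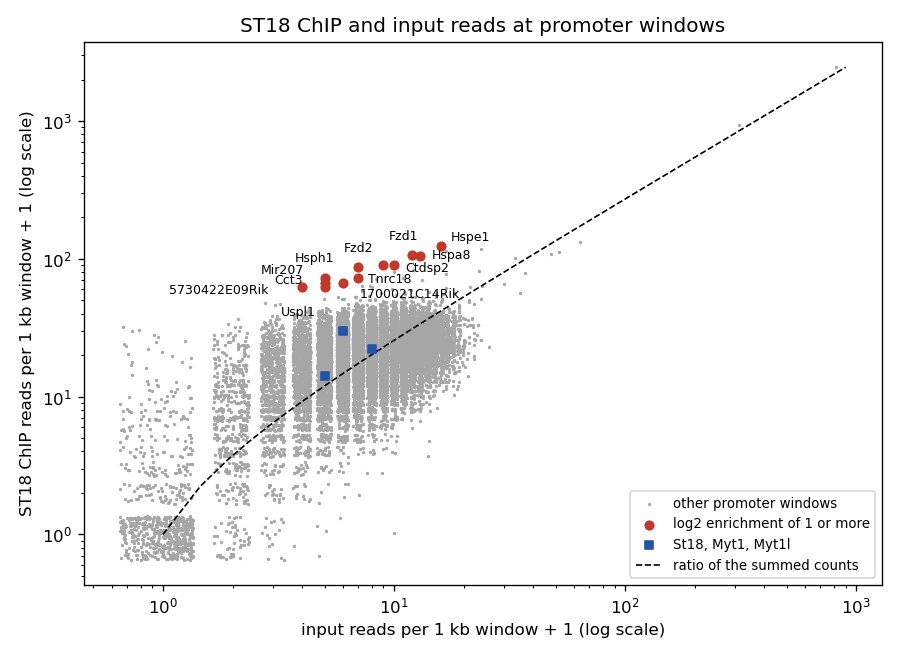
ST18 ChIP reads (vertical axis, log scale) against input reads (horizontal axis, log scale), each plus 1, in promoter windows of 1000 bp, where a point is 1 window and points of other windows are spread slightly to reduce overlap, and the dashed line is the ratio of the summed counts. The 12 windows with a log2 enrichment of at least 1 (red) held 61 to 124 ST18 reads and 3 to 15 input reads, while St18, Myt1 and Myt1l (blue squares) lay among the other windows.

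The exact binomial test with adjustment over all windows called 8 windows higher in ST18 reads, all among those 12: Hsph1 (exact test, adjusted p = 0.0305), Mir207, Fzd1, Fzd2, 5730422E09Rik, Cct3, Hspe1 and Hspa8 (exact test, adjusted p = 0.0495). It called 2 windows lower, Mcm9 with 0 ST18 reads against 9 input reads (exact test, adjusted p = 0.0386) and Tube1 with 3 against 13 (exact test, adjusted p = 0.0419). With counting error alone, the simulated tables held a mean of 0.01 windows at a log2 enrichment of 1 and at most 1. At a threshold of 0.58 the table held 252 windows, against a simulated mean of 84.8 and a highest simulated value of 106. The excess was two-sided: 48 windows lay at least 0.58 below 0, against a simulated mean of 13.7 and a highest value of 25. At an unadjusted exact p under 0.05, 709 windows were lower and 518 higher in ST18 reads, against a simulated mean of 613 in both directions together. No window reached 1.5.

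Across all promoters the enrichment was small. The median log2 value was 0.04 (interquartile range −0.10 to 0.19), the range was −0.76 to 1.21 and the SD across windows was 0.225, against 0.193 in the simulated tables. The number at a log2 enrichment of 1 fell to 6 when the libraries were scaled to their promoter totals and to 7 without windows of 5 or fewer input reads. Windows with a true 2-fold enrichment would mostly not be detectable at this depth.

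The promoters of ST18 and its paralogs were examined next. The St18 promoter itself held 21 ST18 reads against 7 input reads, a log2 enrichment of 0.09 and a ratio 1.10-fold that of all promoters (exact 95% interval 0.449 to 3.05). Myt1 held 29 against 5 reads, at 0.40 and 2.12-fold (0.811 to 7.01), and Myt1l held 13 against 4, at 0.09 and 1.19-fold (0.367 to 5.0). All 3 intervals included 1, so no enrichment was detectable at this depth, and a several-fold one was not excluded for any of the 3.

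The second comparison asked whether promoters of genes with known roles in cortical development stood apart from other promoters. Epithelial-mesenchymal transition genes had the highest list median, 0.17 over 26 promoters, at the 98.9th percentile of random lists. Snai2 and Ctnnb1 (β-catenin) led this list at 0.38 each, followed by Scrt2 at 0.34 and Tjp1 at 0.31, while Zeb2 was lowest at −0.35. Apical progenitor genes had a median of 0.16 over 20 promoters (97.3rd percentile), with Hey1 at 0.50, Emx2 at 0.47, Hes1 at 0.42 and Lhx2 at 0.37, and Hes5 lowest at −0.43. Intermediate progenitor genes lay at the other end, with a median of −0.09 over 16 promoters (1.70th percentile), of which 4 were above the median of all promoters. Eomes (Tbr2), which marks this cell type, was the lowest member, with 12 ST18 and 12 input reads (log2 −0.42, 0.365-fold, 0.150 to 0.890). It did not pass adjustment over all windows (exact test, adjusted p = 0.759). The highest members were Dll1 at 0.33, Insm1 at 0.23, Dll3 at 0.19 and Neurog2 at 0.09.

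None of these 3 lists passed adjustment over the 23 lists (adjusted share 0.252 for each). In all, 4 lists lay outside the central 95% of random lists on either side, against 1.15 by chance. In simulated lists of 26 genes without any change, however, 8% of 50 draws lay above that range. That share covers the upper side only, and the simulated lists were drawn from windows with reads. By the list mean 2 lists lay outside, the HOX clusters and the olfactory receptors, and with a pseudocount of 1 only the olfactory receptors did. Matched on the exact number of reads, 2 lists lay outside, the intermediate progenitor and germ line lists, and neither passed adjustment. The epithelial-mesenchymal transition list lay at the 93.95th percentile, the apical progenitor list at the 94.4th and the intermediate progenitor list at the 1.85th.

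Lists for later stages of cortical development lay within the central range. Neuronal differentiation genes had a median of 0.10 (83.1st percentile of random lists), from Neurod1 at 0.34 to Gap43 at −0.35. Cortical layer genes had a median of 0.10 (84.5th percentile), with Crym at 0.65 (30 against 2 reads), Fezf2 at 0.50, Mef2c at 0.47 and Pou3f1 at 0.41, and Nfib lowest at −0.42. Neuronal migration genes had a median of 0.10 (86.6th percentile), with Flna (filamin A) at 0.58, Cxcl12 at 0.56 and the reelin receptor gene Lrp8 at 0.53, and Rac1 lowest at −0.32. Axon guidance genes (0.03, 41.1st percentile) were led by the netrin receptor genes Unc5b and Unc5c, at 0.42 each, with Epha4 lowest at −0.38. Synapse genes had a median of 0.06 (64.7th percentile), with Gria1 at 0.34 and Slc17a7 lowest at −0.54.

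Notch and Wnt genes had a median of 0.07 (73.4th percentile of random lists) and held the only list members called by the exact test, Fzd1, both over all windows and adjusted over the list alone. Wnt5a followed at 0.61 (32 against 3 reads, 3.90-fold, 1.22 to 19.9, exact test, adjusted p = 0.689), and Hes5 was lowest at −0.43. Chromatin repressor genes (0.03, 42.7th percentile) included Trim28 at 0.69 (36 against 3 reads), Hdac2 at 0.53 and Ezh2 at 0.33, and Sin3b lowest at −0.36 (18 against 14 reads). Cell cycle genes had a median of 0.03 (37.9th percentile), with Ccnb2 highest at 0.47 and Ccnb1 lowest at −0.42. Apoptosis and inflammation genes had a median of 0.08 (79.1st percentile), with the BH3-only gene Bcl2l11 highest at 0.69 (32 against 2 reads) and Bbc3 lowest at −0.29. Ribosomal protein genes had a median of 0.08 (79.1st percentile), a summed ratio 0.993-fold that of all promoters (0.868 to 1.14), and ranged from Rps20 at 0.53 to Rpl30 at −0.57. The ST18 family, with 3 members, lay at the 63.9th percentile.

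Of the lists for other cell types, oligodendrocyte genes had a median of 0.13 (85.6th percentile), pluripotency genes 0.12 (87.1st), microglia genes 0.10 (76.6th), endothelial and mesenchymal genes 0.01 (34.3rd) and astrocyte genes −0.04 (12.4th). Their highest members were Olig1 at 0.46, Tbx3 at 0.42, Tmem119 at 0.44, Cdh5 at 0.61 and Aldh1l1 at 0.27, and their lowest were Nkx2-2 at −0.26, Sall4 at −0.20, Itgam at −0.34, Col3a1 at −0.21 and Gjb6 at −0.31, in the same order of lists. The HOX clusters had a median of −0.01 (8.57th percentile) and a summed ratio 0.837-fold that of all promoters (0.728 to 0.965), from Hoxc5 at 0.34 to Hoxa11 at −0.47. Muscle and liver genes had a median of 0.00 (23.1st percentile), from Myod1 at 0.33 to Fgb at −0.34. Germ line genes, at −0.08 (2.28th percentile, adjusted share 0.252), ranged from Zp1 at 0.27 to Ddx4 at −0.42.

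The 1126 olfactory receptor promoters had a median log2 enrichment of −0.006, below all 10000 random lists (adjusted share 0.0046, the smallest the method can give over 23 lists), and a summed ratio 0.881-fold that of all promoters (0.853 to 0.910). These windows held a median of 16 reads in both libraries together, against 28 over all windows, and their log2 enrichment ranged from Olfr15 at 0.65 to Olfr332 at −0.59. Among random lists matched on the exact number of reads, the median lay at the 32.5th percentile (adjusted share 0.79), so the call was lost.

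**Figure D2:**
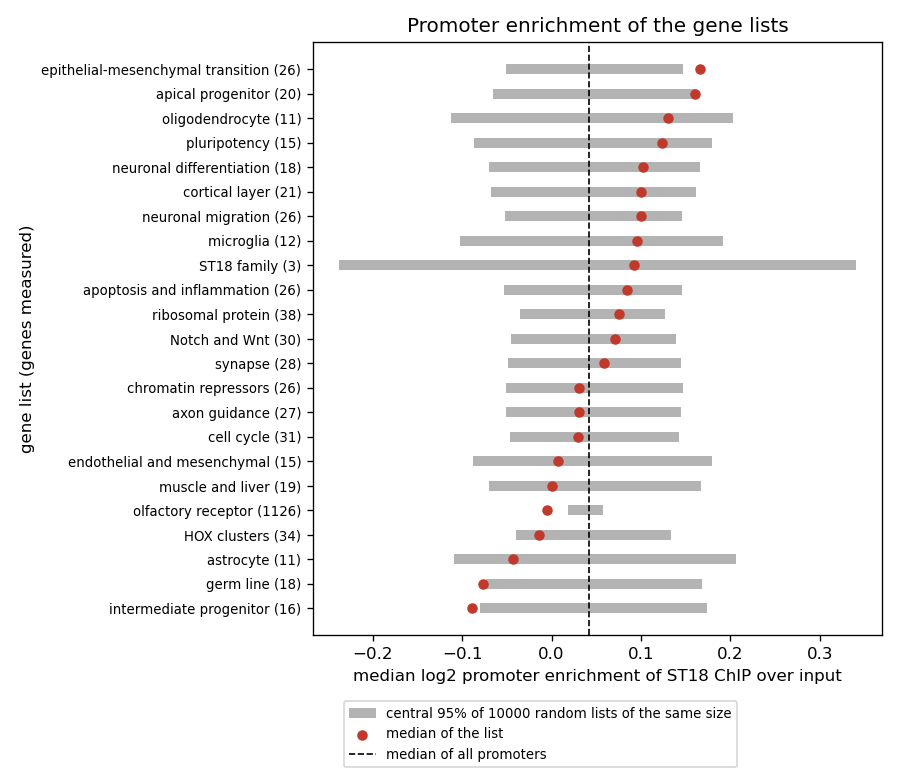
Median log2 promoter enrichment of ST18 ChIP over input (horizontal axis) for each of the 23 gene lists (vertical axis, genes measured in parentheses), with red points for the lists, grey bars for the central 95% of 10000 random lists of the same size and a dashed line for the median of all promoters. Before matching on reads, 4 lists lay outside their bars, of which only the olfactory receptors passed adjustment.

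The third part of the data was the list of peaks, which describes where tags piled up along the genome without reference to input. The labels list it under the input sample and its header names no labelled library, so whether these are peaks of the ST18 ChIP is not settled here. The reads of the ST18 column equal 1.18% of the tags behind the list and those of the input column 0.431%. Promoter windows cover 1.17% of the effective genome, but the tag totals of the labelled libraries were not used here, so this leaves it open. The list held 9381 peaks, of which most were low and short. The median pileup was 9 tags (interquartile range 8 to 11). The median fold over the background was 5.09 (range 1.83 to 196), and 357 peaks (3.81%) had a fold of at least 10. For 4686 peaks (49.95%) that background was the genome-wide average rather than a local one. A length of exactly 48 bp, the fragment length of the peak caller, was shared by 7081 peaks (75.5%), against 73 peaks of 49 bp and 66 of 50 bp, and no peak was shorter. Only 1 of the 357 peaks with a fold of at least 10 was 48 bp long.

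The 10 peaks with the highest fold, in mm9 coordinates, were each between 95 and 348 bp long. The first was on chromosome X from 139917556 to 139917650, with a pileup of 6221 tags and a fold of 196. It was followed by chromosome 12 from 3109951 to 3110096 (fold 184), chromosome 6 from 103599060 to 103599244 (fold 165), chromosome 9 from 35112798 to 35113093 (fold 101) and chromosome 13 from 77578168 to 77578299 (fold 97.0). The next were chromosome 4 from 70039157 to 70039288 (fold 89.3), chromosome 9 from 24346459 to 24346587 (fold 85.2) and chromosome 2 from 98507114 to 98507461 (fold 71.9), the last with the highest pileup of the list, 61233 tags. The other two lay near the start of the assembled sequence of chromosome 9, from 3035690 to 3035917 (fold 70.5) and from 3000017 to 3000229 (fold 68.7). Genes at these positions were not assigned here.

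At the fragment length of the peak caller, 48 bp, at most 96 tags with distinct start positions and strands can cover 1 base. A higher pileup was held by 149 peaks, so tags sharing a position were counted more than once in them. All 10 peaks with the highest fold were among these, with pileups from 301 to 61233 tags. Among peaks at or below 96 tags the highest fold was 39.4, on chromosome 2 from 5300338 to 5300418. Of these 149 peaks, 56 were on chromosome Y, 41 on chromosome 9 and 11 on chromosome X, and 42 lay below 3.2 Mb on chromosome X or an autosome. Without a control library, a peak of this list can also come from regions with many reads in input. Among promoters, the windows with the most ST18 reads, Mir715 (2468 against 814 reads, log2 0.29) and Sfi1 (932 against 309 reads, log2 0.28), were chosen after their values were seen and also held the most input reads.

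**Figure D3:**
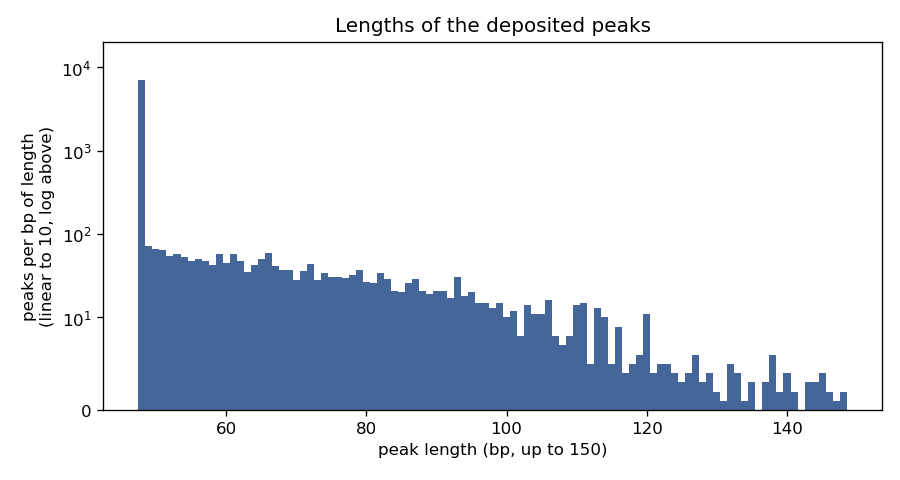
Number of peaks (vertical axis, linear to 10 and logarithmic above) at each length in bp (horizontal axis, long peaks not shown) in the deposited list. The bar at 48 bp holds 7081 of the 9381 peaks, against 73 at 49 bp.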

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

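The settings of log2 1.5 and 0.58, centring, input filter, 1 promoter per symbol, list mean, highest promoter, random lists without olfactory receptors and both stricter peak settings were planned. Scaling, pseudocounts, the exact binomial test, matching on reads and the peak lengths were chosen after seeing the data. The 12 windows at a log2 enrichment of 1 became 252 at 0.58, 0 at 1.5, 7 without windows of 5 or fewer input reads and 6 when scaled to the promoter totals. With a pseudocount of 8 they became 115 and with a pseudocount of 1 they became 2093, and all 12 were still among them, but counting error alone gave a mean of 26 and 1831. Centring left 9 of the 12, and the exact binomial test called 8 of them. The 1 list past adjustment, the olfactory receptors, became 0 with random lists matched on 10 groups of total reads and 0 when matched on the exact total reads (adjusted share 0.0828 and 0.79), and stayed 1 under the other 5 list settings. The 9381 peaks became 704 at −log10 q of at least 10, 2300 without peaks of 48 bp, 2032 also without those above 96 tags or on M and Y, and 9175 at a fold of at least 2 times the lowest. The changes in numbers of windows and peaks follow from how the settings were built. Why the list call was lost is not settled. Using 1 promoter per symbol or the highest promoter per gene moves nothing here, as symbols are unique. The limma test, the fits without each replicate, the replicate correlation and everything that sets peaks against genes were not run. No paired analysis was possible because the deposited ST18 column carries no replicate number and the RNA libraries were not analysed here.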

Other observations

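The families, the genes named below the 10 highest and the tests of explanations in this part were chosen after the result was seen, whereas the ribosomal protein and olfactory receptor lists were fixed before. After the 10 named genes, the next windows in order of log2 enrichment below 1 were Hspd1, the mitochondrial chaperonin, at 0.96 (114 ST18 against 16 input reads), St13 at 0.95 (80 against 9), Chordc1 at 0.95 (70 against 7), Csrp2 at 0.94 (46 against 2), 1110059G10Rik at 0.93 (45 against 2) and Dnaja1 at 0.90 (62 against 6). None of these passed the exact test, with adjusted p from 0.11 for Hspd1 to 0.27 for Dnaja1. Hspe1 with Hspd1, Mir207 with Dnaja1, Cct3 with 1700021C14Rik and St13 with Xpnpep3 are neighbouring genes whose windows both reached 0.8. The genes 5730422E09Rik and Uspl1, with 61 ST18 reads each, lie on either side of Gm8615, which stood at 0.11. The 28 windows at 0.8 or more may thus not all be separate sites, but distances between windows were not measured.

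Families were then formed from gene symbols after the values were seen. The Hsp, chaperonin, Frizzled and Dnaj families had members among the highest windows, which raises their values by selection. The 30 symbols starting with Hsp had a summed ratio 1.47-fold that of all promoters (1.29 to 1.67). Their median lay at the 99.3rd percentile of random lists, and 3 of them reached a log2 enrichment of 1. Without those 3 the ratio was 1.21-fold (1.05 to 1.40), and without Hspd1 as well it was 1.12-fold (0.967 to 1.30). Leaving members out by their enrichment lowers a ratio by construction. The interval for all 30 Hsp symbols counts the neighbours Hspe1 and Hspd1 separately, though their windows may share reads. The 10 chaperonin genes, 9 symbols starting with Cct and Tcp1, were at 1.67-fold (1.29 to 2.20) and the 98.5th percentile. Without Cct3, the only one at a log2 enrichment of 1 or more, the ratio was 1.41-fold (1.07 to 1.87). Of the 10 Frizzled promoters 2 reached a log2 enrichment of 1, Fzd1 and Fzd2, and the family median lay at the 54.0th percentile. The 45 Dnaj promoters (0.987-fold, 0.876 to 1.11), 39 proteasome promoters (0.970-fold, 0.855 to 1.10) and 19 Wnt promoters (1.03-fold, 0.855 to 1.26) had intervals that included 1. So did 23 tubulin and actin promoters (1.147-fold, 0.969 to 1.363, median at the 94.8th percentile) and 52 keratin promoters (1.10-fold, 0.9785 to 1.24). A scan covered all 778 families of symbols sharing their first 3 letters, with at least 5 members each and 100000 random lists per family size. In it 1 family had an adjusted share under 0.05, the 1134 symbols starting with Olf (0.0156, from the smallest share these lists can give). That family holds the 1126 olfactory receptors and a few other genes. The Hsp family had an adjusted share of 0.50 and the 9 symbols starting with Cct, a set without Tcp1, 0.62, so neither passed.

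Across all windows the SD was 0.225 against 0.193 in the simulated tables, so the table varied by more than counting error. Simulated tables with independent reads and the same ratio everywhere held a mean of 0.01 windows at a log2 enrichment of 1. Counting error alone therefore does not account for the 12 such windows, but variation beyond it was not simulated and is not excluded. Low input reads stay open as a part of why these 12 windows reached a log2 enrichment of 1. Of the 12, 5 held at least the median input count of all windows and 7 held fewer. Their high ST18 counts decide nothing, as the formula asks for at least 40 ST18 reads in any such window. Non-specific ChIP signal at highly expressed genes could also contribute. The ribosomal protein promoters, with an upper bound of 1.137-fold, had an interval that included 1. So did 50 translation factor promoters, at 1.07-fold (0.95 to 1.20), but their median lay at the 98.5th percentile of random lists. In the scan the whole Eif family had an adjusted share of 0.469, against 0.50 for Hsp. With neither expression in these cells nor a ChIP without the tagged protein used here, this stays open. Binding of ST18 at these promoters also stays open as a hypothesis, since the design gives no group without ST18 to test it.

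The low enrichment of olfactory receptor promoters was not a product of the pseudocount alone, as the ratio of summed counts, which needs none, had an upper bound of 0.9095-fold. Fewer reads in these windows were tested by splitting the reads at random into equal parts 20 times, matching lists of other genes on one part and taking the ratio in the other, since matching on reads that enter the ratio shifts it by selection. Matched on total reads, other genes had 0.903-fold (central 95% 0.864 to 0.941), with the olfactory value of 0.887 within the range in all 20 splits, and matched on input reads they had 1.01-fold (0.969 to 1.05), with the olfactory value below it in all 20. Total reads consist mostly of ST18 reads and input reads were few, so neither matching settles it, and fewer reads cannot be told apart from a lower ChIP signal. The 332 vomeronasal receptor promoters were at 0.871-fold (0.808 to 0.939), but did not pass the scan (adjusted share 0.469) and were not matched on reads.

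The 48 bp peaks were 97.0 times as many as those 1 bp longer and none was shorter, consistent with a minimum length set by the fragment length of the peak caller. Tags that all share 1 position would give flat tops with a central summit, but among the 815 such peaks at the lowest pileup of 7 tags, 7.73% had a summit within 1 bp of the middle. Partial stacks and 48 bp peaks of higher pileup were not tested. The highest pileup of a 48 bp peak was 128 tags, above the 96 that distinct positions allow. Tags sharing a position therefore do occur among peaks of this length. No biological explanation was tested for the number of 48 bp peaks.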
